A study of Rattus norvegicus with 96 samples.

How the data were processed

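RNA from the blood of 96 male Fischer rats, depleted of globin mRNA per the labels' protocols, had been amplified, biotin-labelled and hybridised to Illumina rat BeadChips, 1 array per rat, in 16 groups. Per the labels, rats inhaled silica or air on 5 days. The 15 mg/m3 rats and their air rats were killed at weeks 0, 1, 2, 4, 8 and 16, and the 1 and 2 mg/m3 rats and their air rats 16 hours after the last exposure, called week 0 here.

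The deposited non-normalized table holds a probe intensity per array, which the authors read with BeadStudio per the submitters' processing notes, and a detection p-value, per the file headers. Of its per-sample columns 192 were not used. The deposited series table holds normalized log2 values, for which the submitters' processing notes name limma and lumi with no version. They follow the log2 intensity of their own array in 96 of 96 cases (correlation of at least 0.992), with medians between 6.58 and 6.62. Their slope against log2 intensity is 0.862 for dim and 0.980 for bright probes, so their transform is not known. They served as an alternative only.

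Values were computed in R 4.3.3 with limma 3.58.1, with data.table at version 1.17.8. Intensities were background-corrected by the normexp method of limma's neqc with an offset of 16, quantile normalized and taken to log2. The background was inferred from detection p-values, which lie on a grid of 825 steps. 626 rows off that grid on at least 1 array were left out of the background estimate and kept in the data, a change to the stock function made after the data were seen. Of 21792 rows, 12368 had a detection p under 0.05 on at least 4 arrays, and the row with the highest mean value was kept for a gene with several, leaving 12308 genes. Names came through Entrez IDs from the reference for 16866 rows, from the file's symbol without a suffix for 87, and were the file's own for 4839. Arrays detected 7642 to 9970 of the 21792 rows (median 9237.5), counted before filtering and called detected genes below, with a median intensity of 61.5 to 137. The median SE of a silica log2 fold change was 0.10.

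A limma model with a mean per group was fitted to all arrays with moderated t tests, and genes with a Benjamini-Hochberg adjusted p under 0.05 were called. Silica was compared with the air rats of the same dose and week. Interactions compared weeks 16 and 0, all 6 weeks (moderated F) and the doses at week 0. Air groups were compared by F tests and pairwise. 21 gene lists, written from general knowledge before the data were examined, were tested with camera at a preset correlation of 0.01 and again with an estimated one: neutrophil, monocyte, T-cell, B-cell, NK and cytotoxic, erythroid, platelet, eosinophil with basophil and mast cell, interferon, inflammatory mediator, oxidative stress, complement, MHC class II, cell cycle, ribosomal protein, mitochondrial respiratory, glucocorticoid, immediate early, apoptosis, matrix and lysosome. Other lists hold 3 genes of the neutrophil list, 3 of the matrix, 2 of the glucocorticoid, 1 of the monocyte and 1 of the immediate early list. "Adjusted over the list alone" means Benjamini-Hochberg over that list's genes. The mean of a list per rat was compared by an exact permutation test, added after the data were seen.

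The signature was trained on the week 0 rats of 15 mg/m3 alone: genes passing adjusted p and 1.5-fold, or, if under 10 pass, the 50 of lowest p. Each rat's score was compared by an exact permutation test, adjusted over the 7 comparisons. Named genes were the 12 largest rises and falls at week 0 and the 6 largest elsewhere, among passing genes with every silica rat on the same side of the air mean. For these largest rises and falls, 8 of 8 silica rats on the same side is therefore a condition of naming, not a result. Where fewer than 3 passed they were the 3 of lowest p, and from each list up to 4 members of lowest p. For a gene undetected in every rat of a group, the fold was computed against the detection limit and is a lower bound. Comparisons, lists, naming rule and the alternatives of the closing part were set before the data were examined, except where the text says otherwise.

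The fit was tested on data simulated for week 16 against air over 12308 genes. It recovered 61 of 67 genes at 1.5-fold, 66 of 67 at 2-fold and 66 of 66 at 3-fold, with 8 false calls among 12108 unchanged genes and 0 of 20 unchanged lists called. The simulated noise was independent between genes, without column runs, and the lists were random genes. So it cannot tell how many false calls the real, correlated data give. Other splits of the real week 16 rats called up to 177 genes and up to 15 lists. Within groups arrays correlated between 0.977 and 0.996, and 0 pairs were identical.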

Results

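Whole-blood RNA of 96 male Fischer rats was hybridised to Illumina BeadChip arrays, 1 array per rat. Rats inhaled crystalline silica, the mineral dust that causes silicosis, or clean air, and were killed afterwards. At 15 mg/m3, 8 silica rats and 4 air rats were taken at each of 6 intervals up to week 16: weeks 0, 1, 2, 4, 8 and then 16. At 1 and at 2 mg/m3, 8 silica rats and their own 4 air rats were sampled at week 0. The arrays detected between 7642 and 9970 of the 21792 probe rows, with a median of 9237.5, and 12308 genes entered the tests after filtering. Changes are given as log2 fold changes, silica over air, with the standard error (SE) of the limma fit, and adjusted p is limma's with Benjamini-Hochberg correction over those genes. The number of rats, in particular 4 air rats per comparison, limits the precision. Because labels gave no chip, runs of 12 neighbouring columns of the deposited table stood in for it. Arrays of such a run resembled each other (mean residual correlation of 0.14 within runs and -0.03 between them). Runs 1 to 4 hold all air rats of the 15 mg/m3 set and 4 of the 8 silica rats of each of its weeks. Runs 5 to 8 hold the other 4 silica rats and every low-dose rat, so the air rats of the 15 mg/m3 set share no run with low-dose rats.

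The first comparison asked how blood RNA differed at the end of the 15 mg/m3 exposure, the group from which the study built its signature. Ldhc, the testis-type lactate dehydrogenase, rose by 0.64 ± 0.11 (adjusted p = 0.00139), and Fcgr2al1, an Fc receptor family gene, rose by 0.62 ± 0.11 (adjusted p = 0.00139). Both rose in 8 of 8 silica rats, which the naming rule required of the largest rises. They were the 2 genes that passed the test at week 0, and 1113 genes had an unadjusted p under 0.05, where chance gives 615.4. Mrpl43, a mitochondrial ribosomal protein, was the gene of lowest p that did not pass, at -0.37 ± 0.08 (adjusted p = 0.0900). The neutrophil list was higher in the silica rats. None of its 24 measured members passed over all genes, and adjusted over the list alone 7 were higher and 1 was lower. Mmp9, a gelatinase stored in neutrophil granules, stood at 0.51 ± 0.13 (adjusted p = 0.149) and Pglyrp1, a granule protein that binds bacterial peptidoglycan, at 0.55 ± 0.14 (adjusted p = 0.149). The list passed camera at adjusted p = 7.9e-08, but at adjusted p = 0.225 with an estimated correlation. The mean of the list per rat was 0.20 higher in silica, above the air mean in 8 of 8 rats (exact permutation p = 0.00202, 2-sided, the smallest p that the splits of 8 and 4 rats can give). Camera also called the interferon list higher (adjusted p = 5.17e-05, and adjusted p = 0.488 with an estimated correlation), with Oasl at 0.52 ± 0.15 and Cxcl10 at 0.40 ± 0.12, adjusted over the list alone at p = 0.011 each in limma. T-cell genes were called lower (adjusted p = 0.0113, and 0.605 as the adjusted p with an estimated correlation) and inflammatory mediators higher (adjusted p = 0.0104, and adjusted p = 0.488 with an estimated correlation). Each of these 2 calls was lost in 2 of 12 refits that left out 1 array. The T-cell difference ranged from -0.14 to -0.037 in them, and its mean per rat did not pass (exact permutation p = 0.170). Leaving out 1 array moved the count of 2: to 31 without air rat 2, to 1 without air rat 1, to 0 without air rat 3, to 4 without silica rat 5 and to 5 without silica rat 6. In the 12 refits that each left out 1 array, Ldhc did not pass in 1 (highest adjusted p = 0.187) and Fcgr2al1 in 2 (highest adjusted p = 0.0881).

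At week 1, 47 genes passed, 28 higher and 19 lower, against 1383 at an unadjusted p under 0.05. Among the largest rises were Stfa2l2 and Il1r2. The neutrophil list was higher, while the monocyte list was not shown to differ (exact permutation p = 0.992). Stfa2l2, of the stefin A family of protease inhibitors, rose by 0.87 ± 0.16 (1.83-fold, adjusted p = 0.00165), Cpeb2, an mRNA-binding protein, by 0.69 ± 0.14 (adjusted p = 0.00594) and Hk3, a hexokinase of myeloid cells, by 0.69 ± 0.15 (adjusted p = 0.0144). Il1r2, the decoy receptor for interleukin-1, rose by 0.68 ± 0.13 (adjusted p = 0.00249), Pilrb2l4 by 0.65 ± 0.12 (adjusted p = 0.00249) and Pglyrp1 by 0.63 ± 0.14 (adjusted p = 0.0113). Scaf1, a splicing-associated gene, fell by 0.68 ± 0.13 (adjusted p = 0.00165) and Slc2a1, a glucose transporter, by 0.49 ± 0.11 (adjusted p = 0.0102). Both fell in 8 of 8 silica rats, which the naming rule required of the largest falls. Slc2a1 ranged from -0.66 to -0.20 over the 12 refits that each left out 1 array. Stc2 (-0.62 ± 0.16), Lmtk2 (-0.58 ± 0.15), Vom1r15 (-0.53 ± 0.10) and Tmprss7 (-0.48 ± 0.12) also passed as lower. Stc2 and Vom1r15 were detected on 1 of 8 silica arrays each and Lmtk2 on 2, so the sizes of their folds rest on values near background. In the neutrophil list 5 of the 24 members rose over all genes and 11 adjusted over the list alone, among them Mmp9 (0.61 ± 0.13, adjusted p = 0.00639) and Mmp8, neutrophil collagenase (0.57 ± 0.14, adjusted p = 0.0408). Its camera call held with an estimated correlation (adjusted p = 1.2e-11, and adjusted p = 0.0419 with an estimated correlation), and the mean of the list was 0.30 higher, above the air mean in 8 of 8 rats (exact permutation p = 0.00202). Immediate early genes, markers of sample handling, were also higher, by 0.11 on average in 8 of 8 rats (exact permutation p = 0.00404), though camera did not call them (adjusted p = 0.153). The glucocorticoid list, which holds Il1r2, was called higher (adjusted p = 0.0225, and adjusted p = 0.400 with an estimated correlation), with Dusp1 at 0.43 ± 0.14, and so were inflammatory mediators (adjusted p = 0.0429, and 0.528 as the adjusted p with an estimated correlation). The count of 47 became 110, 81 and 21 without air rats 2, 3 and 1, and 78 and 27 without silica rats 2 and 6. In only the first 4 column runs it was 0. Of 12 such refits, Stc2 and Lmtk2 did not pass in 8 each, Tmprss7 in 7, Mmp8 in 6, Hk3 in 2, and Cpeb2, Pglyrp1, Mmp9 and Slc2a1 in 1 each, while Stfa2l2, Il1r2, Pilrb2l4, Scaf1 and Vom1r15 passed in every refit.

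At week 2, 4 genes passed, all lower. Chordc1, a co-chaperone of Hsp90, fell by 0.51 ± 0.10 (adjusted p = 0.0132), Stip1, an adaptor of Hsp70 and Hsp90, by 0.45 ± 0.10 (adjusted p = 0.0433) and Dnaja1, a co-chaperone of Hsp70, by 0.38 ± 0.08 (adjusted p = 0.0473). Each fell in 8 of 8 silica rats, which the naming rule required of the largest falls. No list of chaperone genes was tested. The remaining gene of the 4 that passed, Hspcal3_predicted, lay outside the naming rule and was chosen after its values were seen (log2 fold change -0.55, adjusted p = 0.00566). None rose, and 1119 genes had an unadjusted p under 0.05. The neutrophil list was 0.05 higher (exact permutation p = 0.360, above the air mean in 7 of 8 rats) and was not called by camera. MHC class II genes, which present antigen on B cells and monocytes, were called higher (camera adjusted p = 8.46e-07, and adjusted p = 0.105 with an estimated correlation). All 12 measured members lay above 0, and 7 passed adjusted over the list alone, with RT1-Db1 at 0.47 ± 0.12 (adjusted p = 0.160 over all genes) and Cd74 at 0.35 ± 0.12 (adjusted p = 0.308). NK and cytotoxic genes were called higher (adjusted p = 0.0201, and adjusted p = 0.681 with an estimated correlation) and erythroid genes lower (adjusted p = 0.0105, and 0.674 as the adjusted p with an estimated correlation). The count of 4 was 0 without air rats 2 or 3, 12 without air rat 1, 2 without air rat 4, 2 without any of silica rats 2, 5, 7 or 8, and 1 without silica rat 3. Of 12 such refits, Dnaja1 did not pass in 11, Stip1 in 9 and Chordc1 in 3.

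At week 4, 14 genes passed, 1 higher and 13 lower, and several of the lower ones were near the detection limit. RT1-CE11, an MHC class I gene, was detected in all 4 air rats and in 0 of 8 silica rats, at least 1.40-fold lower in silica (adjusted p = 1.09e-05). Ldb2, a LIM-domain binding factor, fell by 0.47 ± 0.10 (adjusted p = 0.0220), Qng1 by 0.43 ± 0.09 (adjusted p = 0.0220), C13h1orf116 by 0.44 ± 0.10 (adjusted p = 0.0393) and C3ar1, the C3a receptor, by 0.42 ± 0.09 (adjusted p = 0.0369). Vpreb1a, a pre-B-cell gene, was detected on 1 air array and on 0 silica arrays (at least 1.15-fold lower on average, adjusted p = 0.0393). Its log2 value was 6.18 in air rat 1 and 5.1 to 5.155 in the other air rats, so the difference rests on that rat. Arhgap18, a GTPase-activating protein, rose by 0.40 ± 0.09 (adjusted p = 0.0499). The neutrophil list was higher, 0 of 24 members passing over all genes and 9 adjusted over the list alone, such as Il1r2 (0.52 ± 0.13, adjusted p = 0.0595) and Mmp9 (0.49 ± 0.13, adjusted p = 0.0754). Its camera adjusted p was 2.12e-08, but adjusted p = 0.104 with an estimated correlation, and its mean was 0.22 higher, above the air mean in 8 of 8 rats (exact permutation p = 0.00202). Without air rat 2, the lowest of the air rats by far (7.42, others 7.70 to 7.72), it was 0.14 higher. Called higher by camera and lost in the same way were platelet genes (adjusted p = 0.402 with an estimated correlation), inflammatory mediators (adjusted p = 0.435 with an estimated correlation), immediate early genes (adjusted p = 0.236 with an estimated correlation) and matrix genes (adjusted p = 0.104 with an estimated correlation). In 12 refits that each left out 1 array, these calls were lost in 2, 5, 3 and 1. Inflammatory mediators ranged from 0.039 to 0.16 and matrix genes from 0.075 to 0.26. Unadjusted p was under 0.05 for 1153 genes. The count was 0 without air rat 1, which had the fewest detected genes of all arrays. It was 89, 94 and 87 without air rats 2, 3 and 4, and 23, 28, 9, 7 and 2 without silica rats 3, 5, 6, 7 and 8. It was 1 in the authors' deposited values. Of 12 such refits, Arhgap18 did not pass in 8, Vpreb1a in 5, C13h1orf116 in 4, Qng1 in 3, Ldb2 and C3ar1 in 2 each and RT1-CE11 in 1.

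At week 8, 34 genes passed, 33 higher and 1 lower, and 7 of the higher ones were members of the neutrophil list. Nos2, inducible nitric oxide synthase, rose 2.35-fold (1.23 ± 0.30, adjusted p = 0.0393), Stfa2l2 2.06-fold (1.04 ± 0.16, adjusted p = 2.99e-05), and Mmp8 1.70-fold (0.76 ± 0.14, adjusted p = 0.00145). Prok2, a secreted prokineticin of neutrophils, rose by 0.76 ± 0.17 (adjusted p = 0.0196) and Pglyrp1 by 0.76 ± 0.14 (adjusted p = 0.00130). Further rises were those of Hk3 by 0.72 ± 0.15 (adjusted p = 0.0101), Il1r2 by 0.64 ± 0.13 (adjusted p = 0.00518) and S100a8, a calcium-binding alarmin, by 0.62 ± 0.13 (adjusted p = 0.00787), each in 8 of 8 silica rats. The naming rule required 8 of 8 silica rats of the largest rises. Drd5, a dopamine receptor, passed as lower at -0.37 ± 0.09 (adjusted p = 0.0196). It was detected on 1 of 8 silica arrays, so the size of its fold rests on values near background. Of the 24 neutrophil genes 15 rose adjusted over the list alone. The list passed camera with a preset correlation (adjusted p = 7.9e-21) and with an estimated one (adjusted p = 0.00102), and its mean was 0.37 higher, above the air mean in 8 of 8 rats (exact permutation p = 0.00202) and in the 4 of 4 column runs that hold both. Klrb1b, an NK-cell receptor, rose by 0.64 ± 0.14 (adjusted p = 0.0101) and Ifit1, an interferon-induced gene, by 0.72 ± 0.14 (adjusted p = 0.00161). Camera called 9 lists besides the neutrophil one, each lost with an estimated correlation. Interferon (adjusted p = 0.419 with an estimated correlation), inflammatory mediator, glucocorticoid and matrix genes (adjusted p = 0.149 with an estimated correlation for each) were higher. Immediate early and apoptosis genes (adjusted p = 0.141 with an estimated correlation for both) and lysosome genes (adjusted p = 0.215 with an estimated correlation) were higher, and MHC class II and erythroid genes (adjusted p = 0.263 with an estimated correlation for both) lower. Immediate early genes are markers of sample handling, and their mean was 0.14 higher in silica (exact permutation p = 0.00202). Unadjusted p was under 0.05 for 1141 genes. The count was 92 when only these 12 arrays were fitted, 8 without air rat 4, 12 without air rat 2 and 19 without silica rat 3, and the adjusted p of Nos2 rose to 0.319 in the worst of its 12 refits, 6 of which did not pass. Drd5 did not pass in 4, Prok2 in 3, Hk3, Il1r2, S100a8 and Klrb1b in 2 each and Ifit1 in 1, while Stfa2l2, Mmp8 and Pglyrp1 passed in every refit.

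At week 16, 586 genes passed, with 379 higher and 207 lower, and 75 and 16 of these changed at least 1.5-fold, against 2250 at an unadjusted p under 0.05. Fetub, a fetuin, rose 2.21-fold (1.15 ± 0.32, adjusted p = 0.0232), Mmp8 2.16-fold (1.11 ± 0.14, adjusted p = 1.75e-07), and Ifitm6, of the interferon-induced transmembrane family, 2.10-fold (1.07 ± 0.16, adjusted p = 6.91e-06). Il22ra2, the soluble interleukin-22 binding receptor, rose by 1.00 ± 0.18 (adjusted p = 0.000214), Zfp532 by 0.90 ± 0.16 (adjusted p = 0.000112) and Mocos, the molybdenum cofactor sulfurase, by 0.83 ± 0.14 (adjusted p = 3.32e-05). Mlf2 fell by 0.70 ± 0.14 (adjusted p = 0.000929), Nabp2, a single-stranded DNA binding protein, by 0.70 ± 0.14 (adjusted p = 0.000513) and Pacc1, a proton-activated chloride channel, by 0.67 ± 0.12 (adjusted p = 9.86e-05). Gpx3, a plasma glutathione peroxidase, fell by 0.65 ± 0.18 (adjusted p = 0.0222), Tbxa2r, the thromboxane receptor, by 0.62 ± 0.18 (adjusted p = 0.0246) and Gas2l1 by 0.61 ± 0.19 (adjusted p = 0.0466). All 12 changed the same way in 8 of 8 silica rats, which the naming rule required of them. The count was 214 without air rat 4 and 308 without air rat 3, and 62 when only these 12 arrays were fitted, fewer than the 92 of week 8 fitted in that way. Fetub depended on the background correction, standing at 0.27 (adjusted p = 0.219 in limma) with stock neqc. The main version differs from it by the change made after the data were seen. Of 12 refits that each left out 1 array, Gas2l1 did not pass in 8, Fetub and Gpx3 in 4 each and Tbxa2r in 3, while the other 8 genes passed in every refit.

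In the gene groups at week 16, 13 of 24 neutrophil genes rose over all genes and 18 adjusted over the list alone, including Mmp9 (0.80 ± 0.13, adjusted p = 1.39e-05), Il1r2 (0.70 ± 0.13, adjusted p = 0.000281) and Fpr1, the formyl peptide receptor (0.43 ± 0.08, adjusted p = 0.000281). The camera adjusted p was 6.7e-20, and adjusted p = 0.00146 with an estimated correlation, and the mean of the list was 0.45 higher, above the air mean in 8 of 8 rats (exact permutation p = 0.00202) and in the 4 of 4 column runs that hold both. Interferon genes rose in 8 of 28 cases, such as Ifit1 (0.67 ± 0.14, adjusted p = 0.000841), higher in 8 of 8 rats, and Ifit2 (0.79 ± 0.19, adjusted p = 0.00533), higher in 7 of 8. The list had adjusted p = 0.000103, and adjusted p = 0.301 with an estimated correlation. Glucocorticoid-responsive genes rose in 5 of 10 cases, such as Sgk1, a kinase (0.37 ± 0.09, adjusted p = 0.00442), and Tsc22d3 (0.38 ± 0.12, adjusted p = 0.0364), with adjusted p = 0.0681 with an estimated correlation. MHC class II genes, carried by B cells and monocytes, were lower, 0 of 12 above 0, with RT1-Db1 falling by 0.44 ± 0.12 (adjusted p = 0.0183) and the list at adjusted p = 0.199 with an estimated correlation. Mitochondrial respiratory genes were lower too, with Uqcrc1 (-0.29 ± 0.08, adjusted p = 0.0214) and Ndufv1 (-0.31 ± 0.09, adjusted p = 0.0279) and adjusted p = 0.0938 with an estimated correlation, and B-cell genes were called lower (adjusted p = 0.0476, and adjusted p = 0.447 with an estimated correlation). Among members of lists that camera did not call, Ptgs2, cyclooxygenase-2 (0.61 ± 0.14, adjusted p = 0.00442), Tlr2 (0.42 ± 0.11, adjusted p = 0.0141) and Nlrp3, the inflammasome sensor (0.54 ± 0.14, adjusted p = 0.0145), rose. Nqo1, a quinone reductase (0.45 ± 0.11, adjusted p = 0.00900), and Klrb1b (0.73 ± 0.14, adjusted p = 0.000370) rose, and Tgfb1, transforming growth factor beta (-0.59 ± 0.14, adjusted p = 0.00644), and Mcm3, a replication helicase subunit (-0.53 ± 0.12, adjusted p = 0.00442), fell. The monocyte list was 0.03 higher (exact permutation p = 0.784). Of 12 refits that each left out 1 array, Tsc22d3 did not pass in 7 (highest adjusted p = 0.162), Tlr2 in 4, Nlrp3 and Uqcrc1 in 3 each, RT1-Db1 and Ndufv1 in 2 each, and Ptgs2, Nqo1, Tgfb1 and Mcm3 in 1 each.

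**Figure D1:**
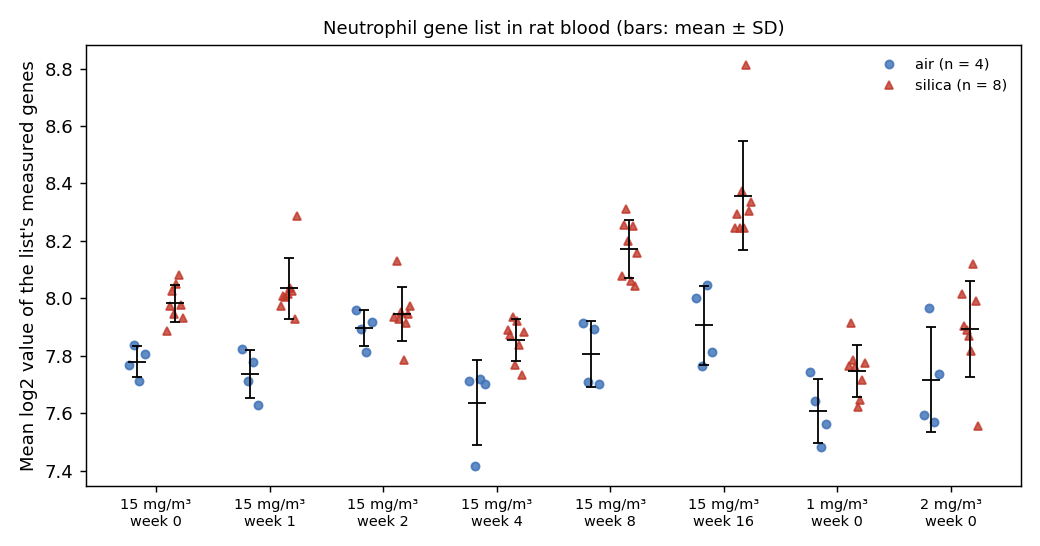
Mean log2 value of the measured neutrophil genes in each rat's blood (y axis, log2 units) by dose and week (x axis), with 4 air rats as circles and 8 silica rats as triangles per comparison and bars for the mean ± SD. At week 16 the silica mean was 8.36 and the air mean 7.91, and at week 2 they were 7.95 and 7.90.

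**Figure D2:**
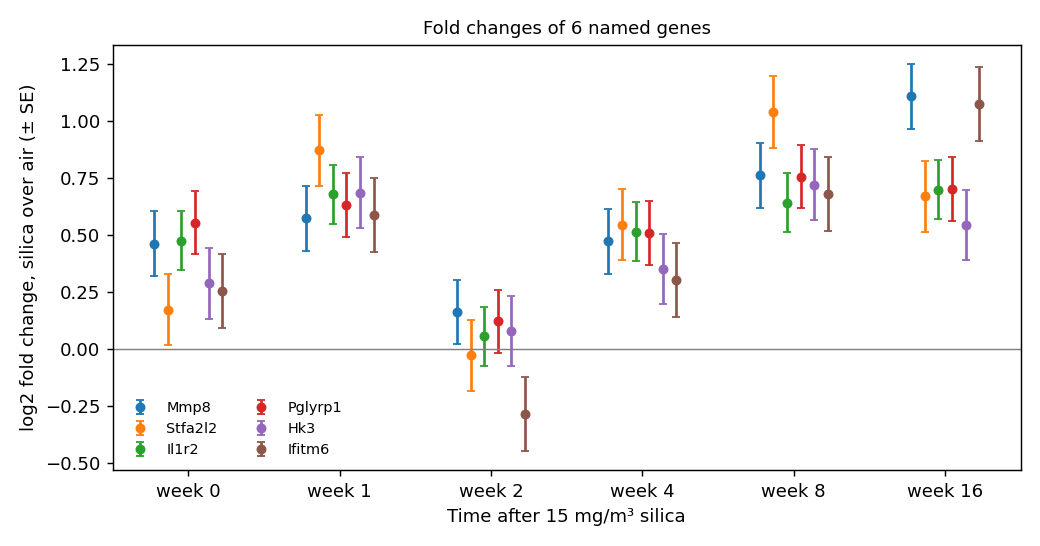
Log2 fold changes, silica over air, of 6 genes at each week after 15 mg/m3 silica (x axis), with bars for the SE of the limma fit. Mmp8 stood at 0.46 at week 0 and at 1.11 at week 16, and Stfa2l2 at 0.17 and 0.67.

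Weeks were compared through the interaction of silica with time. In limma 0 genes differed in their silica effect between week 16 and week 0, with 772 at an unadjusted p under 0.05, and the lowest p belonged to Tbcb, a tubulin cofactor (-0.45 ± 0.10), Rlf (0.59 ± 0.14) and Tmem238 (-0.58 ± 0.14), each at adjusted p = 0.267. Under alternatives 1 gene differed with the replicate block, 1 with column runs as a fixed term and 2 with the stock background correction. Over all 6 weeks the moderated F test called 18 genes, with 1301 at an unadjusted p under 0.05. Among those named here were Ifitm6, Stfa2l2, RT1-Db1, Dnaja1, Chordc1, Tbcb and Rlf. The count was 32, 28 and 30 without air rat 2 of week 4, air rat 4 of week 4 and silica rat 7 of week 16. Weeks 8 and 16 shared 30 higher genes, where independent lists would share 1.02, and weeks 1 and 8 shared 11 (0.0751 for independent lists); each week had its own air rats. As lists, the difference between weeks 16 and 0 passed camera for neutrophil genes, 0.25 on average (adjusted p = 5.78e-07, and adjusted p = 0.192 with an estimated correlation), glucocorticoid genes, 0.18 (adjusted p = 0.0155, and 0.226 as the adjusted p with an estimated correlation), B-cell genes, -0.25 (adjusted p = 0.00173, and 0.226 as the adjusted p with an estimated correlation), MHC class II genes, -0.31 (adjusted p = 5.78e-07, and adjusted p = 0.111 with an estimated correlation), and mitochondrial respiratory genes, -0.075 (adjusted p = 0.0382, and 0.226 as the adjusted p with an estimated correlation). Without air rat 2 of week 0 the B-cell difference was -0.13 (adjusted p = 0.196) and the glucocorticoid difference 0.10 (adjusted p = 0.277), and the mitochondrial call was lost in 8 of 24 refits that each left out 1 array. Adjusted over the list alone, RT1-Db1 differed by -0.68 and Cd74, the invariant chain of MHC class II, by -0.54. Of the 379 genes higher at week 16, 92.3% were above 0 at week 0 and 62.8% at week 2.

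The lower doses asked whether a weaker exposure leaves a trace in blood at week 0. In limma 0 genes passed at 1 mg/m3, with 315 at an unadjusted p under 0.05, fewer than the 615.4 that chance gives. The lowest p belonged to Ifi47 (0.55 ± 0.12, adjusted p = 0.115, higher in 8 of 8 rats), an interferon-inducible GTPase, Ifgga2l2 (0.52 ± 0.13) and Slfn1 (0.61 ± 0.16), both at adjusted p = 0.925. Interferon genes were called higher as a list, with 27 of 28 above 0 and 5 higher adjusted over the list alone. The camera call held with an estimated correlation (adjusted p = 1.41e-17, and adjusted p = 0.0153 with an estimated correlation). The mean of the list was 0.24 higher, above the air mean in 8 of 8 rats, but did not pass over the 21 lists (exact permutation p = 0.0202, adjusted p = 0.187). Its members of lowest p included Ifit3 at 0.58 ± 0.18 and Usp18 at 0.52 ± 0.17, both at a limma adjusted p = 0.033, adjusted over the list alone. Neutrophil genes were called higher, with adjusted p = 0.158 with an estimated correlation and a mean 0.14 higher, above the air mean in 8 of 8 rats, that did not pass either (exact permutation p = 0.0444, adjusted p = 0.187). Camera called 6 lists besides these, all lost with an estimated correlation: NK and cytotoxic and immediate early genes (adjusted p = 0.165 for both), inflammatory mediators and erythroid genes, these lower (adjusted p = 0.0819 for both), and complement and ribosomal protein genes (adjusted p = 0.158 for both). Leaving out 1 array, the complement difference ranged from 0.067 to 0.21 and was lost in 2 of 12 refits. The ribosomal one ranged from 0.027 to 0.089 and was lost in 1. The count was 1 without silica rat 7, and 23 with all 12 week 0 air rats pooled. Those air groups differed among themselves in 1429 genes, so the pooled count can mix silica with this difference.

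At 2 mg/m3 limma again called 0 genes, with 582 at an unadjusted p under 0.05, where chance gives 615.4. Ldhc was highest in rank (0.53 ± 0.11, adjusted p = 0.149, higher in 7 of 8 rats), followed by Arl11 (0.42 ± 0.11) and Arhgap18 (0.35 ± 0.09), both at adjusted p = 0.803. Neutrophil genes were called higher by camera (adjusted p = 2.73e-08, and adjusted p = 0.105 with an estimated correlation), 5 of them adjusted over the list alone, such as Mmp9 (0.37 ± 0.13) and Mmp8 (0.41 ± 0.14). Their mean was 0.18 higher and did not pass either (exact permutation p = 0.125, adjusted p = 0.387). Platelet genes, such as Pf4, platelet factor 4 (0.35 ± 0.10), were called higher (adjusted p = 0.137 with an estimated correlation), though the list turned to -0.039 without air rat 4. Monocyte, inflammatory mediator and lysosome genes (adjusted p = 0.246 with an estimated correlation for each), immediate early genes (adjusted p = 0.105 with an estimated correlation) and MHC class II genes (adjusted p = 0.397 with an estimated correlation) were called higher, and erythroid genes lower (adjusted p = 0.246 with an estimated correlation). The count was 1 without silica rat 8, and 86 with all 12 week 0 air rats pooled. The pooled air groups differed among themselves in 1429 genes, so that count can mix silica with this difference. No gene's week 0 effect differed between doses in limma: 0 genes between 15 and 2 mg/m3 (356 at an unadjusted p under 0.05), 0 between 15 and 1 (518) and 0 between 2 and 1 (216). Each of these unadjusted counts was below the 615.4 of chance.

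The study built a week 0 signature and tried it in the low-dose rats, and the same was done here. Of the 12 training arrays' genes only Ldhc passed, so the 50 genes of lowest p made the score, 39 of them higher in silica, including Pglyrp1, Mmp8 and Fcgr2al1. The score averages signed log2 values against the training air rats, with a threshold of 0.21 midway between the training groups. At 1 mg/m3 it was 0.16 higher in silica (0.22 ± 0.07 against 0.06 ± 0.09, SD, n = 8 and 4, exact permutation p = 0.00404, adjusted p = 0.00943), with 8 of 8 rats above the air mean but 3 above the threshold. At 2 mg/m3 it was 0.21 higher but did not pass (0.38 ± 0.19 against 0.18 ± 0.15, exact permutation p = 0.0990, adjusted p = 0.0990), with 7 of 8 silica rats and 1 of 4 air rats above the threshold. With the 8 low-dose air rats pooled the result turned round, 0.10 and not passing at 1 mg/m3 and 0.27 and passing at 2 mg/m3. At 15 mg/m3 it was higher at week 1 by 0.29 and at week 8 by 0.33 (exact permutation adjusted p = 0.00707 for both), at week 16 by 0.48 (exact permutation adjusted p = 0.0106) and at week 4 by 0.20 (exact permutation adjusted p = 0.0255), and was not at week 2, by 0.10 (exact permutation adjusted p = 0.0943). Week 4 did not pass without air rat 2 (0.10), air rat 4 (0.22), or week 0 air rats 1 (0.17) and 3 (0.12). Week 2 passed without air rat 1 (0.13) and silica rat 3 (0.11), and 2 mg/m3 passed without silica rat 8 (0.26).

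**Figure D3:**
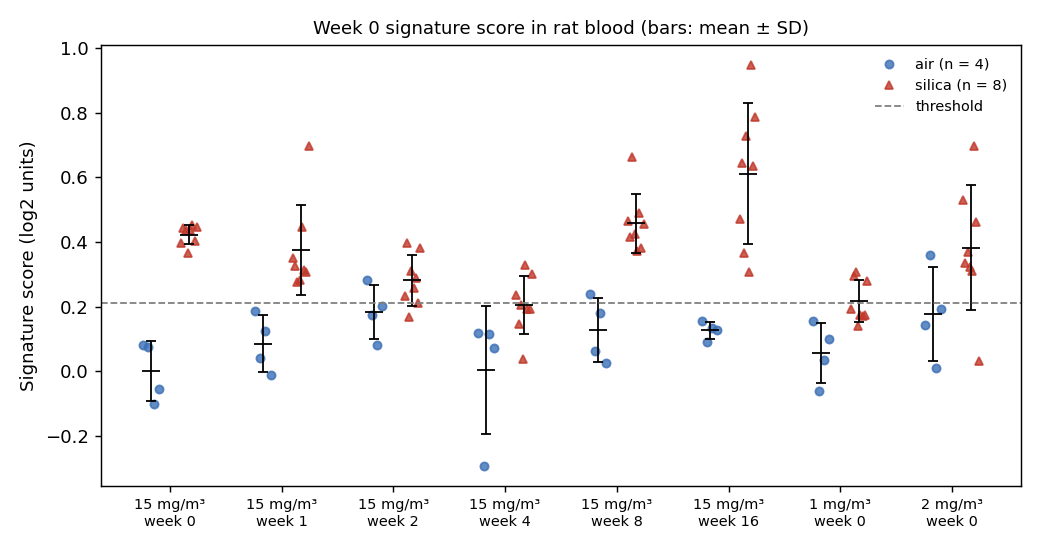
Signature score of each rat (y axis, log2 units) by dose and week (x axis), with 4 air rats as circles and 8 silica rats as triangles per comparison, bars for the mean ± SD and a dashed line at the threshold. The week 0 rats of 15 mg/m3 are the training set, and at weeks 1, 8 and 16 8 of 8 silica rats were above the line, with 1 of 4 air rats at week 8. At week 2 6 of 8 silica rats and 1 of 4 air rats were above it, and at week 4 3 of 8 silica rats and 0 of 4 air rats.

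Air rats without silica also differed. Among the 3 week 0 air groups 1429 genes differed in limma's F test. Against the air rats of the 15 mg/m3 set, 1134 genes differed in the air rats of the 1 mg/m3 set and 1171 in those of the 2 mg/m3 set, and 14 differed between the low-dose sets. Myo9b, an unconventional myosin, was 1.15 ± 0.17 higher and Cd38, a NAD-consuming surface enzyme, 1.34 ± 0.25 lower (log2 -1.34, adjusted p = 7.76e-05) in the 1 mg/m3 air rats, and Nos2 stood at -1.33 ± 0.35. The count was 913 without air rat 4 of the 15 mg/m3 set. Between weeks, 3817 genes differed among the air rats, from 408 between weeks 8 and 0 to 2056 between weeks 16 and 0. Each count against week 0 used the same week 0 air rats, which also differed from the low-dose air rats of week 0. Ank1, for one, was 1.00 and 1.04 higher in the 1 and 2 mg/m3 air rats and 1.05 higher at week 8. In the air rats, time against week 0 thus cannot be told apart from a difference of that group, and genes shared in this way were not counted. Silica rats were compared in the same way, 8 per week, in addition to the comparisons listed above. They differed from week 0 in 1802, 1427, 3050, 1106 and 3047 genes at weeks 1, 2, 4, 8 and 16. These counts use no air rats, but time since silica goes with time in them. At 1.5-fold, 37 were higher and 70 lower at week 1, against 211 and 159 in air rats. At week 4 these were 286 and 32, against 272 and 120. Among air rats Gpr4, a proton-sensing receptor, was 1.67 ± 0.21 higher and Rpl3, a ribosomal protein, changed by -0.87 ± 0.14 at week 16 against week 0. The lists of eosinophil, basophil and mast cell (smallest adjusted p = 0.0519), oxidative stress (smallest adjusted p = 0.171) and cell cycle genes (smallest adjusted p = 0.0577) passed camera in no silica comparison. The genes of the air rats given here were picked after their values were seen.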

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

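The tests of a lower lymphocyte share, of column runs for the week 16 count and the air groups, of the size of the folds, of other lists as covariates, and of other splits were chosen only after the results were seen. In 14 of 148 outlier tests, each of 1 score, count or gene within a group, 1 rat stood far from the others. Independent tests would give 7.4 by chance, but these share rats and measures, so 7.4 is only a rough guide. Signature scores were 0.66 in silica rat 3 of week 8 (others 0.37 to 0.49), 0.70 in silica rat 8 of week 1 (others 0.28 to 0.45) and -0.29 in air rat 2 of week 4 (others 0.07 to 0.12). The neutrophil list mean was 7.42 in that air rat (others 7.70 to 7.72), 8.81 in silica rat 6 of week 16 (others 8.25 to 8.37) and 8.29 in silica rat 8 of week 1 (others 7.93 to 8.04). Air rat 1 of week 1 had 7727 detected genes (others 8969 to 9160). Single genes far from the other rats were Scaf1 at 6.13 in air rat 3 of week 1, Dnaja1 at 10.24 in silica rat 4 of week 2, Vpreb1a at 6.18 in air rat 1 of week 4, Prok2 at 9.89 in silica rat 6 and Drd5 at 5.31 in silica rat 1 of week 8, and Mocos at 9.02 in silica rat 6 and Pacc1 at 6.39 in silica rat 2 of week 16. The silica effect differed among weeks in 18 genes, and between weeks 16 and 0 in neutrophil (0.25), B-cell (-0.25), MHC class II (-0.31), mitochondrial (-0.075) and glucocorticoid (0.18) lists by camera with a preset correlation, and in 0 of these 5 lists with an estimated one.

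Neutrophil genes were higher at weeks 8 and 16, and the values argue against column runs as the whole source. They go against a fall of lymphocytes alone only if neutrophil and monocyte genes scale alike, and cannot decide about sample handling. In the 4 column runs that hold air rats of this set, with 1 silica and 1 air rat of each week, the silica rat had the higher list mean in 8 of 8 pairs. A lower share of lymphocytes alone would raise monocyte genes alike, if the genes of both lists scale alike, which was not tested. The neutrophil minus monocyte mean was 0.31 higher at week 8 (exact permutation p = 0.00404) and 0.42 at week 16 (exact permutation p = 0.0101). The monocyte mean was 0.05 and 0.03 higher (exact permutation p = 0.331 and 0.784). Because a fall of lymphocytes and monocytes together could give the same difference, the neutrophil minus monocyte mean cannot decide about such a joint fall. After the immediate early score, a marker of sample handling, 0.23 of 0.37 was left at week 8 (exact permutation p = 0.00404). At week 16 0.38 of 0.45 was left (exact permutation p = 0.00202). A noisy score removes too little, and this score covers only handling that changes these genes. What was left therefore cannot decide about handling. More neutrophils in blood, or more of these RNAs per neutrophil, may explain the higher list mean, and no cell counts are given in the sources used here.

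In the fit of all arrays 586 genes were called at week 16, more than at any other week, but with only the groups compared 62 were, against 92 at week 8. With a term for column runs 675 were called, so runs do not explain the count. With the neutrophil list mean as a covariate 1 of the 586 stayed, the result that a neutrophil share as the source predicts. The covariate goes with silica, since the lowest silica rat (8.25) was above the highest air rat (8.05), and other list means also ended many calls: 151 stayed with the glucocorticoid, 190 with the interferon and 248 with the mitochondrial list. The median fold of these genes fell only in part, from 0.41 to 0.26, so 62.8% was left, while the median SE went from 0.11 to 0.12, so the calls ended through smaller folds with somewhat larger errors. A changed neutrophil share may be part of the source, but for the whole folds it cannot be told apart from another response to silica that goes with it.

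The week 0 air rats of the 15 mg/m3 set differed from the low-dose air rats. The 2 sets share no column run, and a term for runs rests on the 15 mg/m3 silica rats, which are in all 8. With that term 1721 genes differed, and with detected genes per array as a covariate 1592, so neither accounts for the 1429. The exposure set and the time of death go with these groups and stay open, untested.

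Other splits of the same rats, 100 per result, were counted, the real one included. Only the real split gave as many genes at week 1 (47, highest other 37, in 1 split), week 8 (34, highest other 1, in 1 split), week 16 (586, highest other 177, in 1 split) and with week in air rats (3817, highest other 699, in 1 split). With 100 splits the smallest possible share is 1 in 100, and there was no correction for the number of results. For these counts in the fit of all arrays chance is thus unlikely but not excluded, least clearly at week 1. The splits were run in that fit alone. The week 1 count itself was 21 without air rat 1, 27 without silica rat 6 and 3 with only the groups compared, and the week 16 count 62 with only the groups compared. Other splits gave more genes than the real one at week 2 (4, highest other 10, in 4 splits), among weeks (18, highest other 24, in 2 splits) and among the week 0 air groups (1429, highest other 1543, in 2 splits). Their shares are under 5 in 100, and chance is not called excluded for them. The week 2 count was also 0 without air rat 2 or air rat 3. The other split of the air groups as large as the real one kept all 4 air rats of the 15 mg/m3 set together. Chance cannot be excluded at week 0 (2, highest other 293, in 21 splits) or week 4 (14, highest other 543, in 35 splits), and splits calling so many genes point to structure among these rats. In each comparison with 0 genes all 100 splits gave as many, with highest others of 20 at 1 mg/m3, 58 at 2 mg/m3, 428 between weeks 16 and 0, 180 between 15 and 2, 38 between 15 and 1 and 40 between 2 and 1 mg/m3. For lists called by camera with a preset correlation, only the real split gave as many at week 8 (10, highest other 8, in 1 split), where chance is unlikely but not excluded. Of these 10 only the neutrophil list passed with an estimated correlation. Chance cannot be excluded for the number of lists at week 0 (4, highest other 8, in 45), week 1 (3, highest other 10, in 36), week 2 (3, highest other 10, in 54), week 4 (5, highest other 10, in 26), week 16 (6, highest other 15, in 23), 1 mg/m3 (8, highest other 13, in 18) or 2 mg/m3 (8, highest other 13, in 17).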

How the results depend on the processing

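The tests with column runs, stock neqc and without the 2 arrays of fewest detected genes were chosen only after the results were seen. The plan named neqc itself, and the main version of it was changed after the data were seen, so stock neqc is the unchanged function. Values are counts of genes at 15 mg/m3 unless stated, and the cause of each change was not tested. At adjusted p under 0.01 the counts were 16 at week 1, 1 at week 2, 1 at week 4, 12 at week 8, 228 at week 16, 6 among weeks, 744 among air groups and 2405 with week in air rats. With a fold of at least 1.5 they were 15, 0, 1, 20, 91, 8, 363 and 896. At adjusted p under 0.10 they were 100 at week 1, 59 at week 4, 99 at week 8, 973 at week 16 and 56 among weeks. With all 12 week 0 air rats pooled they were 265 at 15, 23 at 1 and 86 at 2 mg/m3, which can mix silica with the differences among those air groups. With the 8 low-dose air rats pooled they were 29 at 1 and 29 at 2 mg/m3, with signature differences of 0.10 at 1 mg/m3 (not passing) and 0.27 at 2 mg/m3 (passing). The signature with no fold limit holds 1 gene and passed at 2 mg/m3 (0.53). With array weights they were 74 at week 1, 2 at week 2, 1 at week 4, 73 at week 8, 1 at 1 mg/m3 and 1 at 2 mg/m3. With the authors' deposited values they were 25 at week 1 and 1 at week 4, with quantile normalization without background correction 31 and 1, with an offset of 50 31 and 1, with no filter 2 at week 2 and 62 at week 4, and with genes detected in at least 50% of arrays 1 at week 4. With column runs as a fixed term they were 16 at week 0, 12 at week 2, 32 at week 4, 1 between weeks 16 and 0 and 70 among weeks, and as a random block 7 at week 0, 42 at week 4, 53 at week 8 and 63 among weeks. With only the groups compared they were 1, 3, 0, 0, 92 and 62 at weeks 0, 1, 2, 4, 8 and 16, and 605 among air groups. With only the first 4 column runs they were 1, 0, 1, 0, 5 and 180, and 2 among weeks. With stock neqc they were 4 at week 0, 25 at week 1 and 2 between weeks 16 and 0, and without the 2 arrays of fewest detected genes 21 at week 1, 2 at week 2 and 0 at week 4. With an estimated correlation 4 of 52 list calls were left. The platelet list at 2 mg/m3 turned to -0.039 without air rat 4.

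With the replicate number as a block (replicate block) the counts were 1 at week 2, 6 at week 4, 1 at 1 mg/m3, 1 at 2 mg/m3 and 1 between weeks 16 and 0. The numbers do not pair the rats: 18 arrays correlated best with their own number, where shuffles gave 13.2 on average and 28 at most. The block changed no other count by over 1.5 times, but with it 5 of the 52 list calls no longer passed camera.

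Leaving out 1 array at a time, counts ranged from 0 to 31 at week 0, 21 to 110 at week 1, 0 to 12 at week 2, 0 to 94 at week 4, 8 to 43 at week 8, 214 to 707 at week 16, 0 to 1 at 1 and 0 to 1 at 2 mg/m3, 13 to 32 among weeks, 913 to 1785 among air groups and 3364 to 3957 with week in air rats. They stayed from 0 to 0 for weeks 16 against 0 and for each pair of doses, and the number of list calls ranged from 48 to 56. Of the 52 list calls 23 passed in every refit and 29 were lost in at least 1, such as B-cell genes at week 16 in 5 and inflammatory mediators at week 1 in 7 of 12. Signature differences ranged from 0.12 to 0.19 at 1 mg/m3, 0.13 to 0.27 at 2 mg/m3, 0.23 to 0.32 at week 1, 0.062 to 0.13 at week 2, 0.10 to 0.24 at week 4, 0.23 to 0.37 at week 8 and 0.34 to 0.53 at week 16. Of 77 passing results of named genes 25 passed in every refit and 52 were lost in at least 1, Dnaja1 at week 2 in 11 of 12. With only the groups compared, 57 of 163 results of named genes no longer passed and 5 newly passed. With only the first 4 column runs, 52 of 140 no longer passed and 0 newly passed. Testing each probe row on its own or with an intensity trend and robust settings moved 0 of 15 counts by over 1.5 times. A BeadChip block was not run, since no file names the chip, and column runs took its place. Signal over background limits genes near the detection limit, such as Vpreb1a and Stc2.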

Other observations

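The tests of week 16 genes in other comparisons, and the choice of the genes given here, came only after the results were seen. Of the 379 genes higher at week 16, 93.4% were above 0 at 2 mg/m3, 78.6% at 1 mg/m3, 91.0% at week 8, 87.6% at week 1 and 78.4% at week 4. Of the 207 lower, 81.2% were below 0 at 2 mg/m3, 58.0% at 1 mg/m3 and 51.2% at week 2. Each comparison had its own air rats. The shares themselves were not tested against chance, since genes of a rat do not vary independently.

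Nos2 was 2.35-fold higher in silica at week 8 and also 1.33 lower (log2 -1.33) in the air rats of the 1 mg/m3 set than in those of the 15 mg/m3 set. Gpx3, which fell by 0.65 at week 16, stood at -0.97 in the air rats of the 2 mg/m3 set. Both genes thus varied among air rats by as much as with silica.

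Dnaja1, lower at week 2, was higher at week 16 (0.38, adjusted p = 0.00250 in limma).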
